A study of Mus musculus with 2 samples.

How the data were processed

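Paraformaldehyde-fixed frozen sections, 10 µm thick, of duodenum and colon from 1 male (replicate 1) and 1 female (replicate 2) C57Bl6 mouse aged 6 to 10 weeks were imaged with the MERSCOPE platform after staining of cell boundaries and photobleaching. The authors deposited 1 table of counts per region, 2 regions per animal, with each value a count of transcripts of 1 gene in 1 segmented cell. Each table holds 140 genes and 40 blank barcodes. All 140 symbols were found in the reference gene table. The submitters' processing notes name Seurat. Its version and role, and the settings of transcript decoding and cell segmentation, are not given in the sources used here.

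Marker lists, gene lists, groupings, tests and the rule for named genes were fixed before the data were examined. Alternatives chosen later are named as such. The panel carried 15 of the fixed cell class markers, with 5 for enteric glia, 5 for enteric neurons and 2 for epithelium. Cells with at least 10 panel counts (1392 of 31893) were scaled to their total, log-transformed and clustered with the Leiden method (15 neighbours, resolution 1, seed 0), first on the marker genes as planned and then on all panel genes with 20 principal components, a choice also fixed in advance. A cluster was named only with at least 3 fixed markers of 1 class. No doublets were removed, and mixing of neighbouring cells by the segmentation was not corrected. No glia-like cluster was found, so the planned comparisons of glia were not made. Tests of glial-marker cells (at least 2 glial marker counts) and of Piezo2-positive cells of any kind took their place and were chosen after seeing the data.

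Regions within an animal, and the 2 animals, were compared by summed counts over all cells, per 10000 panel counts and per cell, with exact Poisson intervals for levels and exact binomial intervals for ratios and shares. Gene ratios over all cells were fixed in advance between the animals only, and between regions they were planned for glia. Such comparisons have 1 sample per side and no test, and numbers of changed genes were tabulated but are not reported for that reason. Named genes are up to 10 in each direction with the largest ratio, at least 100 counts over both sides and intervals that do not overlap; not every gene that meets this rule is reported. Members of fixed lists, leading genes of clusters and genes shown beside them were named outside this rule. On simulated Poisson counts with 20 genes changed 4-fold, the interval rule recovered 22 of the 24 changed genes that reached 100 counts between the male regions, 202 of 214 between the female regions and 217 of 238 between animals, with changed genes under 100 counts left out as in the data, and marked 0.719%, 1.53% and 1.07% of unchanged genes. Simulated counts fell independently, whereas real counts clump in cells: 20 cells held 33.3% of the counts of male region 0. The error of the rule on the real counts may therefore be larger.

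Cell groups were tested on counts summed per animal and group, with the animal as a block, by the edgeR quasi-likelihood test. Genes had at least 50 counts, with Benjamini-Hochberg adjustment at 0.05. The library size was the total panel counts without the glial markers for glial-marker cells, and without Piezo2 for Piezo2-positive cells. Levels per animal in these tests use the same totals, while levels of glial-marker cells within a region keep the markers in the total. SE values were derived from the F statistic and the log2 fold change. For tested comparisons, named genes had to pass adjustment. None did, so the genes shown were chosen after their values were seen, apart from Piezo2. Simulated sums (20 simulations, 12 changed genes each) gave the recovered shares quoted. Alternatives were TMM factors, counts per cell, DESeq2, no count filter, minimums of 5 and 25 counts per cell, no animal block, 1 animal at a time, mixed cells left out, at least 2 Piezo2 counts, and thinning to 10 counts per cell. Co-detection was set against the number of cells that depth alone predicts. Depth is low: the median cell held 0 counts in 3 regions and 1 in female region 1, and cells with at least 10 counts held 50.4%, 12.9%, 43.0% and 55.1% of the counts in male regions 0 and 1 and female regions 0 and 1. Software was Python 3.11.15, scanpy 1.11.5, python-igraph 0.11.9, scipy 1.17.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.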

Results

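The panel measured transcripts of 140 genes in sections of mouse duodenum and colon from 1 male and 1 female animal, imaged as 2 regions per animal. The labels do not say which region holds which tissue, so regions carry their numbers below and were not matched between the animals. Intervals in brackets are exact 95% intervals and cover counting error only.

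The transcripts differed in kind as well as in number between the regions. The leading genes of female region 1 were the matrix gene Fn1 and 3 genes used by absorptive epithelium, the water channel Aqp8, the cytoskeletal linker Ezr and the chloride exchanger Slc26a3. The synaptic gene Snap25 and the collagen Col12a1 were among the 5 leading genes of each of the other 3 regions, with the growth factor receptor Fgfr1 first in both male regions. The gastric-type mucin Muc6 was the most abundant gene of female region 0. Depth differed with this: male region 0 held 7775 cells with 3048 panel counts, male region 1 held 4068 cells with 582, female region 0 held 6343 cells with 4288, and female region 1 held 13707 cells with 45942. Mean counts per cell were 0.392, 0.143, 0.676 and 3.35 in the same order, or 0.307 in the male and 2.51 in the female (1.41 ± 1.55, mean ± SD, n = 2 animals). Cells with no count at all made up 88.6%, 91.2%, 77.2% and 44.6%. Fgfr1 gave 2182 of every 10000 panel counts in male region 0 (2019 to 2354), Muc6 gave 1423 in female region 0 (1312 to 1540), and Fn1 and Aqp8 gave 830 each in female region 1. Blank barcodes, which match no gene, took 1.39%, 1.19%, 3.36% and 1.23% of all counts, and 46, 53, 23 and 93 genes lay above the highest blank of their region.

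**Figure D1:**
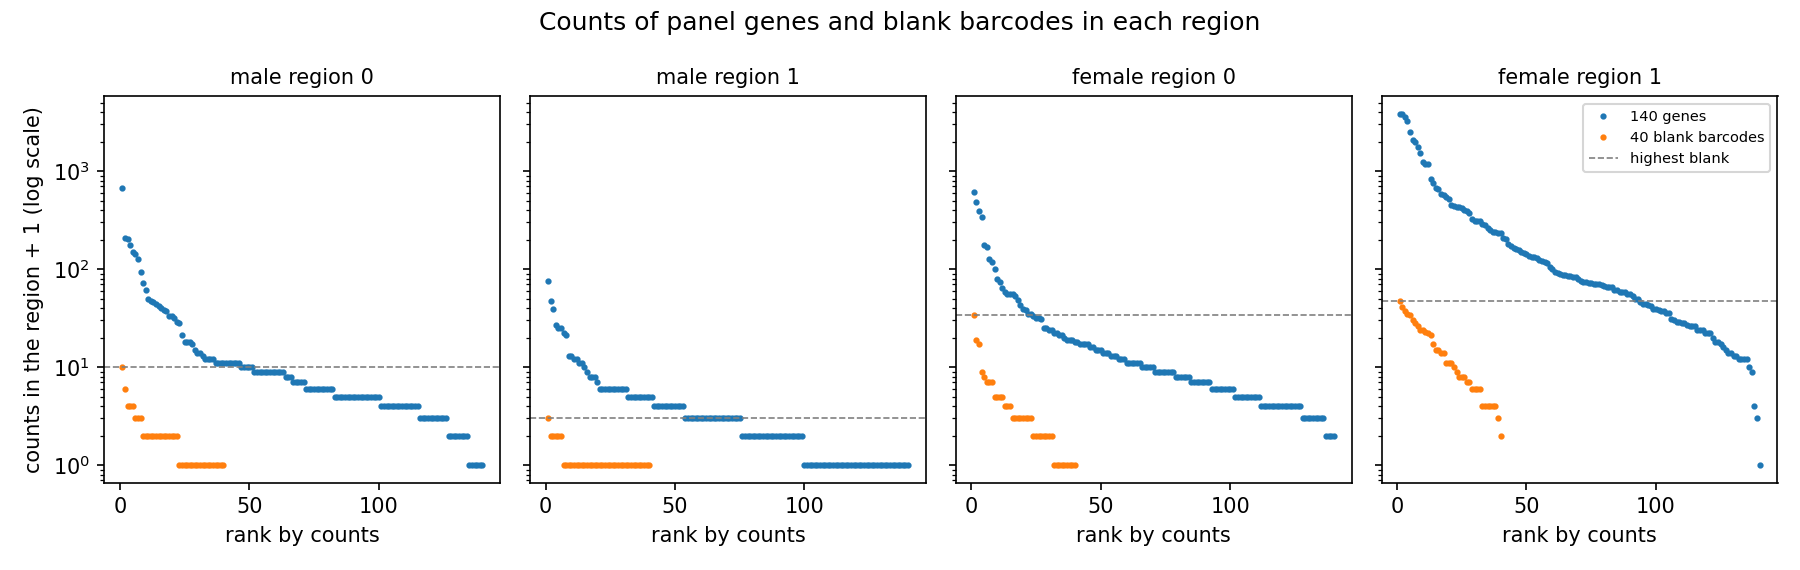
Counts of each gene and of each blank barcode in the 4 regions. Genes are ordered within each region by their counts.

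Among the cells with at least 10 counts, female region 1 split into groups led by epithelial transport genes, matrix genes, muscle genes and neuronal genes. These cells numbered 55, 4, 77 and 1256, and grouping them on all panel genes gave 11 clusters. Clusters 6, 7 and 8 carried Ezr, the apical constriction gene Shroom3, Aqp8 and Slc26a3, and made up 12.3%, 24.0% and 10.9% of the female region 1 cells. Cluster 2 (16.2%) carried the chloride channel gene Cftr, the transporter Slc12a8 and the potassium channel gene Kcnn4, and cluster 9 (5.33%) carried Cftr and Ctnnb1. Cluster 3 (19.2%) was led by Fn1, the intermediate filament gene Vim, the guidance factor Slit3 and the growth factor receptor Pdgfra. Cluster 5 (10.0%) was led by Des, the kinase gene Dmpk and the calcium channel gene Cacna1c, and on 3 and 4 counts it also held more of the neuronal markers Elavl4 and Stmn2 than the other cells. Cluster 10 held 22 cells, 1.75% of the region (1.10 to 2.64), and was the only cluster with 3 of the fixed markers of a cell class. It was enteric neuron-like, with Tubb3 at 56.4-fold and Stmn2 at 47.2-fold the level of the other cells, besides Syt1, the synuclein Sncg and the nicotinic receptor gene Chrna3. Over the whole region Tubb3, Stmn2 and Syt1 each had fewer counts than its highest blank. With minimums of 5 or 25 counts per cell, settings not fixed in advance for all panel genes, no cluster was named. With Piezo1 and Piezo2 left out of the clustering, also chosen after seeing the data, no cluster had cluster 10 as its main source. Names were not assigned in that setting. The panel held 1 fixed marker each of smooth muscle and fibroblasts and 2 of epithelium, so the other clusters were not named.

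**Figure D2:**
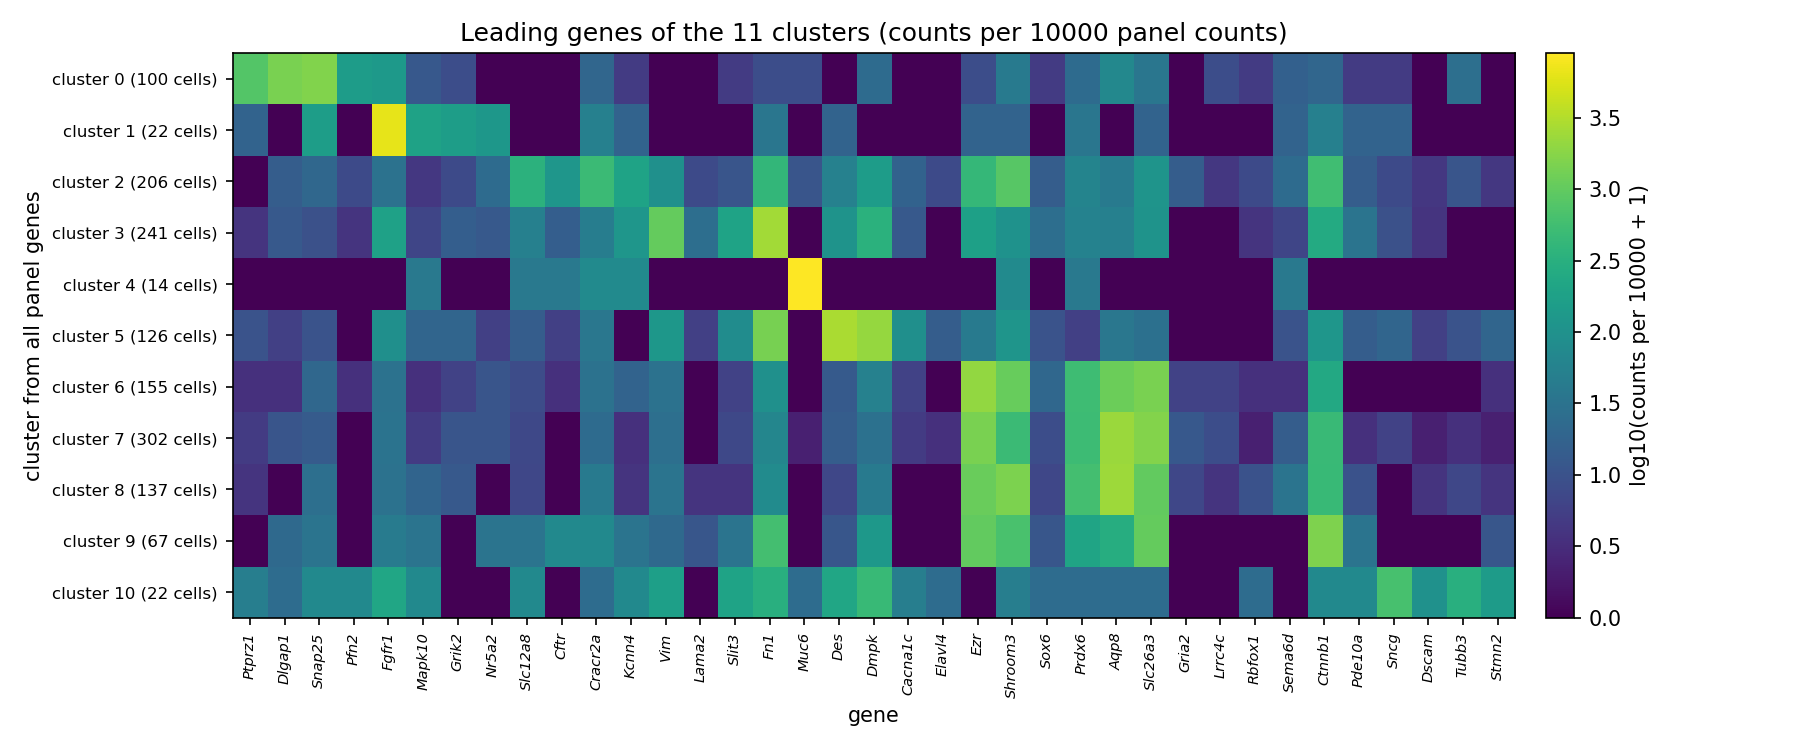
Levels of the leading genes in the 11 clusters made from all panel genes. The genes also made the clusters, so the levels describe them and test nothing.

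The deep cells of the other 3 regions formed clusters that female region 1 almost lacked. Cluster 0 joined Snap25, Dlgap1, the receptor phosphatase Ptprz1 and the presynaptic scaffold Pclo with the transporter gene Abca8b. Cluster 1 was a group of Fgfr1-rich cells, and cluster 4 held almost nothing but Muc6. Cluster 0 had 100 cells and made up 65.5% of the cells with at least 10 counts in male region 0 (51.4 to 77.8), 4 of 4 in male region 1, 76.6% in female region 0 (65.6 to 85.5) and 0.0796% in female region 1 (0.00202 to 0.443). Its Snap25 level was 1577 per 10000, its Dlgap1 level 1428 and its Ptprz1 level 787. All 59 male cells with at least 10 counts lay in cluster 0 or 1. Cluster 1 held 19 cells of male region 0 out of 22, with Fgfr1 at 6417 per 10000 (5779 to 7107), and cluster 4 held 14 cells, each from female region 0, with Muc6 at 8973. A cluster found in so few libraries may reflect those libraries, and none of the 3 was named.

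**Figure D3:**
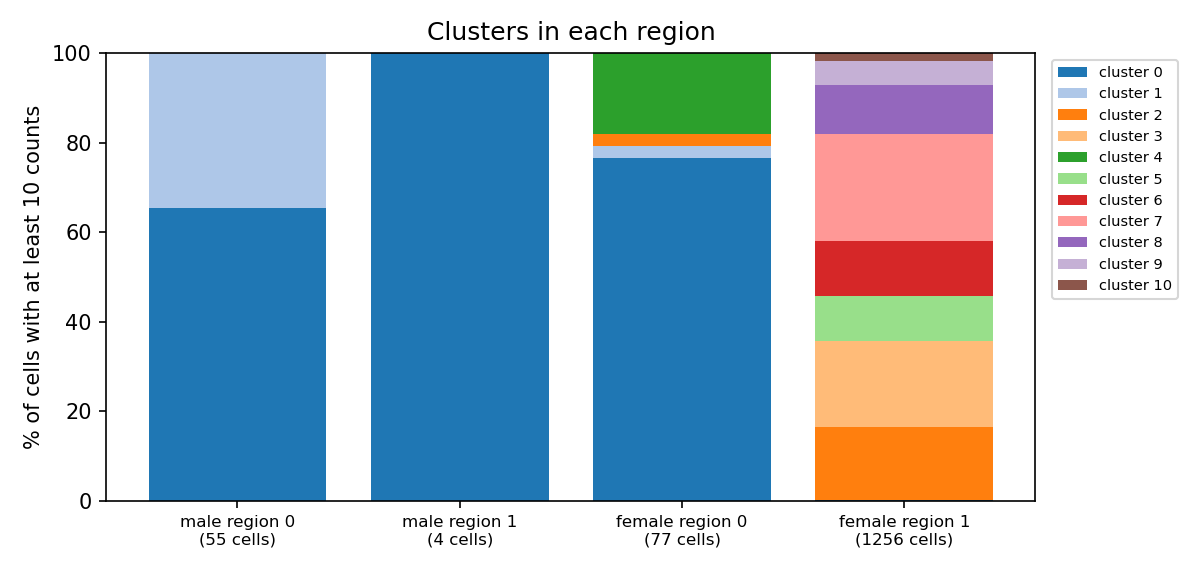
Share of each cluster among the cells with at least 10 counts. Male region 1 has only 4 such cells.

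Within the female animal, region 1 was richer in genes of absorptive epithelium and in stromal and muscle genes, and region 0 in the mucin Muc6 and in synaptic genes. Both fixed epithelial markers on the panel, Slc26a3 and Aqp8, were higher in region 1, as were the stromal genes Fn1, Vim, Pdgfra and Slit3 and the muscle gene Des. Snap25, Dlgap1 and Pclo, which serve synaptic release and scaffolding, were higher in region 0, with the neurturin receptor Gfra2. With 1 section per region there was no test. Per 10000 panel counts, region 1 exceeded region 0 by 30.5-fold for Slc26a3 (16.6 to 63.7), 18.2-fold for Vim (8.33 to 49.7), 17.8-fold for Aqp8 (11.5 to 29.1), 15.5-fold for Fn1 (10.3 to 24.4), 14.3-fold for Des (7.76 to 29.9), 13.8-fold for Prdx6 (6.99 to 32.1), 12.6-fold for Pdgfra (5.37 to 38.9), 10.8-fold for Ezr (7.60 to 15.9) and 9.61-fold for Slit3 (3.26 to 46.9). Region 0 exceeded region 1 by 121-fold for Dlgap1 (83.5 to 183), 65.5-fold for Snap25 (51.5 to 84.2), 36.1-fold for Pclo (24.6 to 54.3), 10.2-fold for Abca8b (7.67 to 13.6), 9.24-fold for Col12a1 (8.04 to 10.6), 8.97-fold for Gfra2 (6.47 to 12.4), 7.40-fold for Tgfbr3 (5.84 to 9.34) and 6.57-fold for Prickle2 (5.41 to 7.95). Muc6 had 610 counts in region 0 and 11 in region 1. The lower side of many of these ratios is no higher than background: the 9 genes higher in region 1 had fewer counts in region 0 than its highest blank (33), and Dlgap1, Pclo and Muc6 had fewer in region 1 than its highest blank (46), so their folds are imprecise beyond counting error. Counting per cell multiplies every ratio by the same factor, and these genes kept their direction, at 151-fold for Slc26a3 in region 1 and 13.2-fold for Snap25 in region 0, while Syt4 was 4.67-fold higher in region 0 per 10000 counts and turned to 1.06-fold in favour of region 1 per cell (0.766 to 1.49). Of the matrix genes, Col18a1 went with Fn1 (3.73-fold higher in region 1) and Col12a1 went the other way.

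Within the male animal, Ptprz1, Dlgap1, Abca8b and Fgfr1 were higher in region 0. Ptprz1 and Dlgap1 are 2 of the genes that led cluster 0, and Fgfr1 led cluster 1. Per 10000 counts the ratios, region 0 over region 1, were 26.9 for Ptprz1 (4.75 to 1071; 141 counts against 1), 2.35 for Dlgap1 (1.31 to 4.66), 1.82 for Abca8b (1.16 to 3.00) and 1.72 for Fgfr1 (1.35 to 2.21), with the same direction per cell. Among cells with at least 10 counts, Abca8b turned to 1.35-fold in favour of region 1 (0.531 to 2.88), which has 4 such cells, and the Dlgap1 ratio of 1.82 no longer excluded 1. Without clusters 0, 1 and 4 the Fgfr1 ratio fell to 1.27, with an interval that spans 1. Among cells with at least 10 counts Fgfr1 had 384 counts in region 0 and 0 in the 4 cells of region 1. The exact upper bound of that ratio, region 1 over region 0, was 0.198, but it takes counts as independent. In region 0, 19 of the 55 such cells lay in the Fgfr1-rich cluster 1, and in region 1 0 of 4 did. The bound does not cover the draw of so few cells. The settings with at least 10 counts and without clusters 0, 1 and 4 were chosen after seeing the data. The single Ptprz1 count of region 1 is no higher than its highest blank.

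Between the animals, the stromal genes Vim and Fn1, the muscle genes Des and Dmpk, and Ezr and Gucy2c (the guanylin receptor) were higher in the female. Ptprz1, Fgfr1, the kinase gene Mapk10 and Abca8b were higher in the male. Of the matrix genes, Col12a1 went against Fn1, 3.52-fold higher in the male per 10000 counts, and turned to 2.32-fold higher in the female per cell. The synaptic genes Snap25, Dlgap1 and Pclo and the receptor Gfra2 were higher in the male per 10000 counts and higher in the female per cell, so their direction rests on the scale. Gfra1 was higher in the male per 10000 counts and stood at 1.16-fold in favour of the female per cell (0.759 to 1.81). There is 1 animal per sex, so these values describe 2 animals and were not tested. Per 10000 counts the female exceeded the male by 42.5-fold for Vim (11.7 to 351), 37.2-fold for Des (12.7 to 180), 32.7-fold for Ezr (16.6 to 75.8), 22.0-fold for Dmpk (10.1 to 60.0), 21.9-fold for Gucy2c (6.03 to 181) and 18.5-fold for Fn1 (11.2 to 33.1). The male exceeded the female by 19.8-fold for Ptprz1 (15.2 to 25.9), 17.1-fold for Fgfr1 (15.3 to 19.05), 17.01-fold for Mapk10 (12.0 to 24.3) and 15.1-fold for Abca8b (12.4 to 18.3), and per cell by 2.43-, 2.09-, 2.08- and 1.84-fold. In male region 0 the 6 female-higher genes named here had fewer counts than the highest blank, as had Ptprz1 and Mapk10 in female region 1, while in male region 1 Fn1, Ezr and Dmpk lay above its highest blank of 2. Snap25 was 6.20-fold higher in the male per 10000 counts (5.33 to 7.21) and 1.32-fold higher in the female per cell. With female region 1 left out, an alternative chosen after seeing the data, the female ratios fell to 2.54 for Vim (0.454 to 25.7), 2.82 for Des (0.727 to 16.0), 3.28 for Ezr (1.48 to 8.26), 8.89 for Dmpk (3.86 to 25.1), 7.62 for Gucy2c (1.82 to 67.7) and 1.30 for Fn1 (0.649 to 2.68), with intervals that span 1 for Vim, Des and Fn1. The epithelial markers Slc26a3 and Aqp8, 15.8- and 17.3-fold higher in the female with both regions, then stood at 0.564 (0.227 to 1.34) and 1.06 (0.521 to 2.18). Of these 8 genes only Dmpk lay above the highest blank of female region 0. Fgfr1 stayed higher in the male, 5.20-fold per 10000 counts and 2.36-fold per cell, and Mapk10 4.43- and 2.01-fold, with fewer Mapk10 counts in female region 0 than its highest blank. Abca8b was 2.64-fold and Ptprz1 2.15-fold higher in the male per 10000 counts, but per cell they stood at 1.20 (0.939 to 1.53) and turned to 1.03 in favour of the female (0.768 to 1.36). Snap25 (1.62-fold), Dlgap1 (1.80-fold) and Pclo (1.92-fold) were then higher in the female, and Gfra2 stood at 1.07 (0.745 to 1.54).

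**Figure D4:**
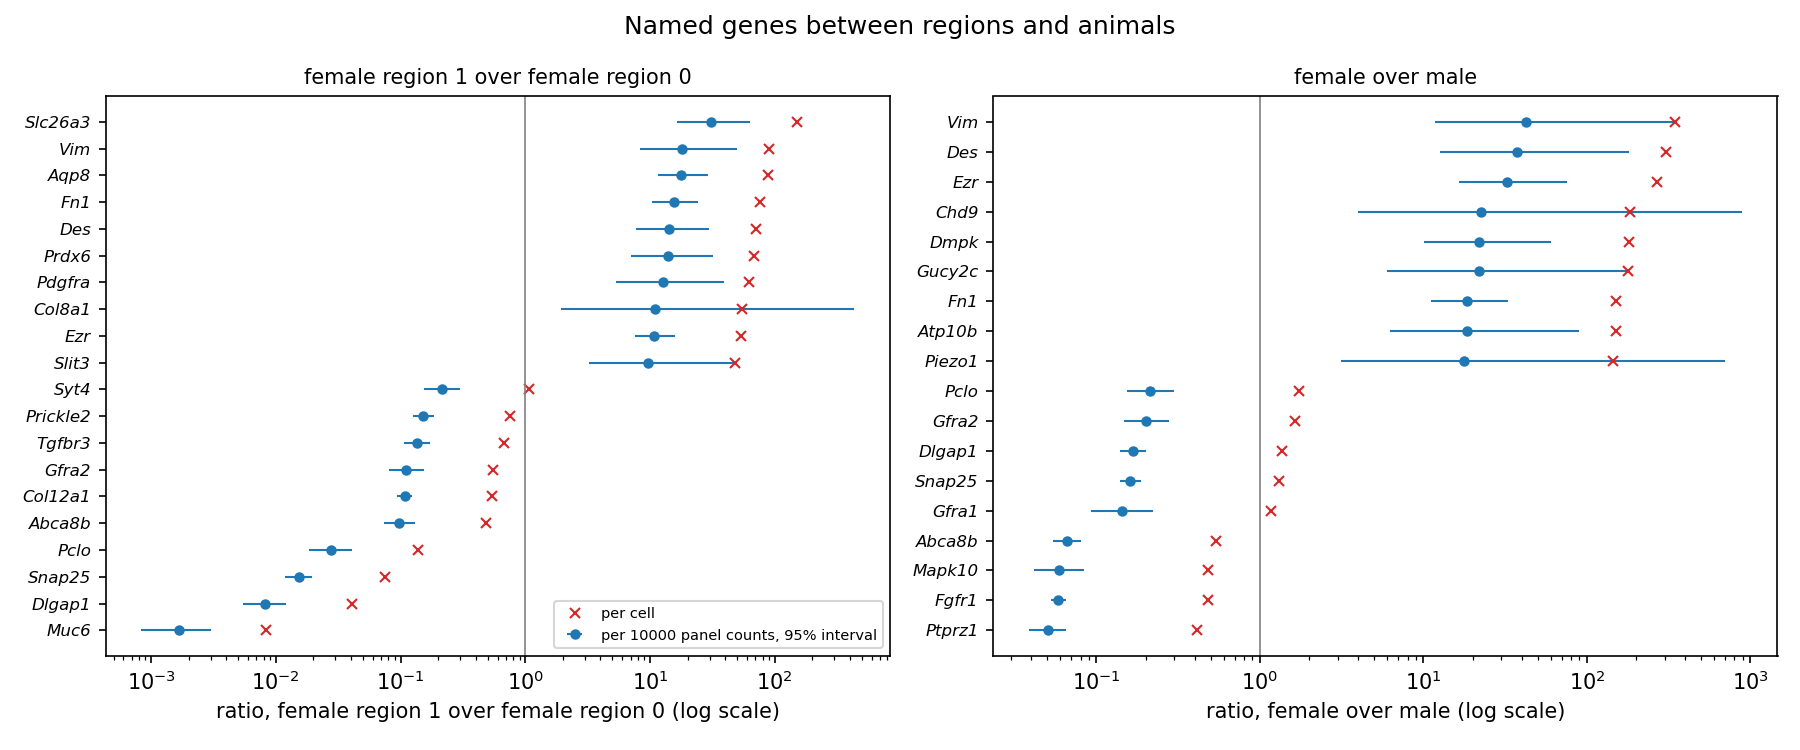
Ratios of the named genes between the female regions and between the animals, per 10000 panel counts with intervals and per cell. Per cell, Syt4 turns between the female regions, and Pclo, Gfra2, Dlgap1, Snap25 and Gfra1 turn between the animals, Syt4 and Gfra1 to ratios whose intervals span 1.

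Glial transcripts were few. S100b and Cdh19, which mark enteric glia and Schwann cells, rose above the highest blank in female region 1 and in male region 1, S100b did so in male region 0, and no glial marker did so in female region 0. The 5 glial markers of the panel gave 61, 11, 71 and 229 counts in male regions 0 and 1 and female regions 0 and 1. Clustering on the marker genes, the planned route to enteric glia, gave 18 clusters and none with 3 markers of 1 class, so the comparisons of glia with other classes, with neurons, between regions and by Piezo2, and the glial subclusters, were not made. Cells with at least 2 glial marker counts, a definition used in their place after seeing the data, numbered 10, 0, 11 and 9. Of those with at least 10 counts, 9 of 9 in male region 0 and 10 of 10 in female region 0 lay in cluster 0, against 0 of 6 in female region 1. Of all cells with at least 10 counts, 65.5%, 76.6% and 0.0796% lay there in the same order, so the last value says nothing about glial-marker cells. The make-up of the neuronal marker counts differed too: Snap25 made up 92.8% of neuronal marker counts in male region 0 (88.6 to 95.8), 97.4% in female region 0 (95.6 to 98.6) and 41.6% in female region 1 (34.5 to 48.9), where each of the other neuronal markers lay under the highest blank. In female region 1, Tubb3 met Sncg in 9 cells, 8.52 times as many as cell depth alone predicts (3.90 to 16.2).

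Glial-marker cells had higher fitted levels of Ptprz1, Dlgap1 and Pclo than the other cells, but no gene passed the test. Ptprz1 is a phosphatase of glial precursors, and Dlgap1 and Pclo are synaptic scaffold genes. The test set 9 male and 16 female glial-marker cells against 50 and 1317 others, summed per animal (2 animals, 57 genes). edgeR called 0 genes, with 0 at an unadjusted p under 0.05, and DESeq2 called 0. The log2 fold changes were 3.45 for Ptprz1 (SE 3.06, adjusted p 0.938), 2.97 for Pclo and 2.31 for Dlgap1, higher in both animals. The female part largely restates the contrast of its regions, since 10 of the 16 female glial-marker cells but 67 of the 1317 others came from region 0. Within female region 0, glial-marker cells held 820.05 Ptprz1 counts per 10000 against 264 and 957 Pclo counts against 349, but 1367 Dlgap1 counts against 1418. The Ptprz1 contrast there is uncertain, since 1 cell of the region held 35 counts. The glial-marker cells held 36 in all and the others 37, so these totals do not say which group that cell belongs to. Piezo2 came to 0.11 (SE 2.16, adjusted p 0.975), with 310.1 against 178 per 10000 in the male and 16.6 against 32.2 in the female. On simulated sums with this spread, edgeR recovered 9.17% of genes changed 16-fold, so the test had little power.

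Piezo2, a stretch-gated cation channel, and its relative Piezo1 were found in cells of several clusters, in a different order. Piezo2 was highest in the Snap25- and Ptprz1-bearing cluster 0, a rank that rests on the male animal, and came next in the Fn1- and Pdgfra-bearing cluster 3 and the Des-bearing cluster 5. Piezo1 was highest in cluster 3. Cluster 7, rich in Aqp8 and Slc26a3, held little of either. Piezo2 had 37, 1, 21 and 172 counts in the 4 regions, above the highest blank in male region 0 and female region 1 and under it in the other 2. In cluster 0 the highest blank stood at 87.8 per 10000, and in its cells of female region 0, at 124, above Piezo2. Per 10000 counts it stood at 183 in cluster 0 (135 to 243; 306 in its male cells and 97.5 in its female cells, 54.6 to 160.8), 86.5 in cluster 3 (58.4 to 124), 54.8 in cluster 5 (28.3 to 95.7) and 13.9 in cluster 7 (6.94 to 24.9). A single cell gave 13 of the 33 Piezo2 counts in the male cells of cluster 0, a clumping that these intervals do not cover. Piezo1 stood at 107 in cluster 3 (75.1 to 147) and 2.53 in cluster 7, and had no count in cluster 0 (upper bound 14.1). In clusters made without the 2 channel genes, an alternative chosen after seeing the data, Piezo2 stood at 182 in the counterpart of cluster 0. Cluster 3 split there, and Piezo2 stood at 68.8 and 85.7 in its counterparts. Between the female regions, Piezo1 was 3.72-fold higher in region 1 (1.68 to 10.2). The Piezo2 ratio, region 1 over region 0, was 0.764 per 10000 counts (0.485 to 1.27), and per cell it turned to 3.79. Piezo2 was 2.72-fold higher in the male per 10000 counts (1.87 to 3.87) and turned to 3.00-fold higher in the female per cell. The same single male cell gave 13 of the 38 male counts.

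**Figure D5:**
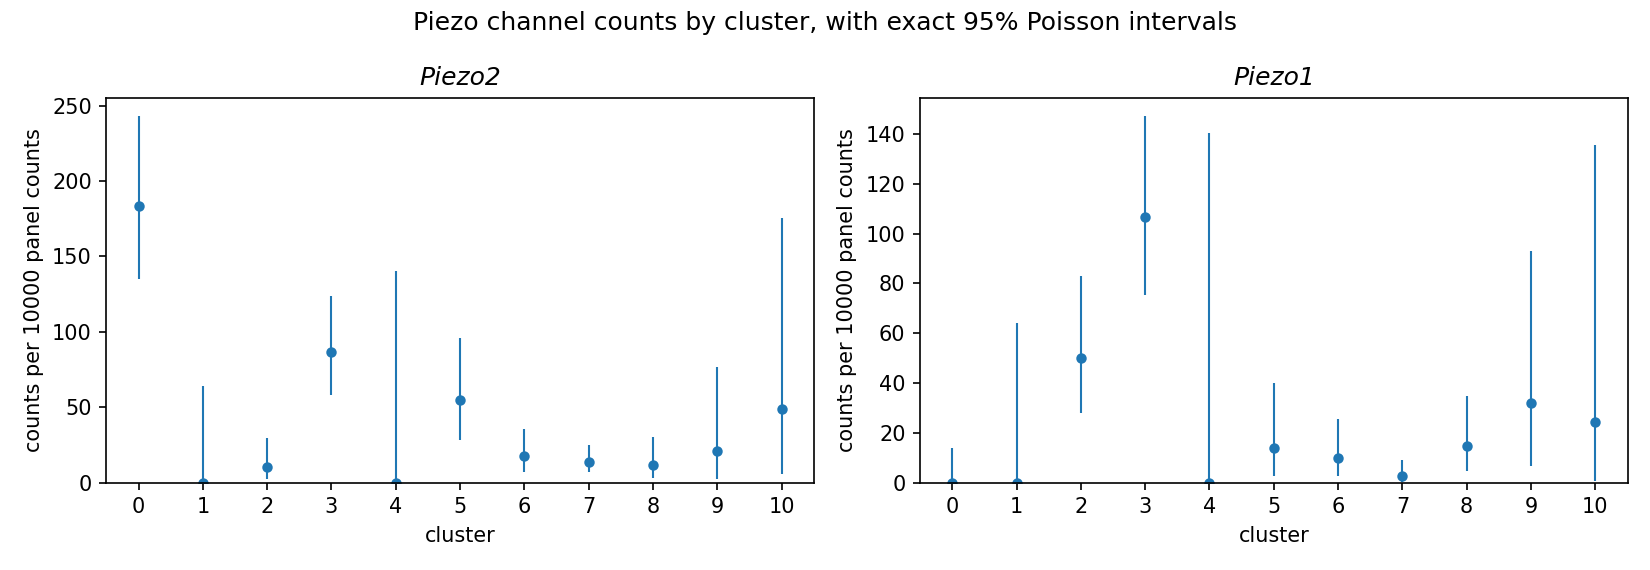
Piezo2 and Piezo1 per 10000 panel counts in each cluster, with exact intervals. Clusters 0, 1 and 4 lie mainly outside female region 1.

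Piezo2 was detected in 4 of 10 male glial-marker cells (40%; 12.2 to 73.8) and 1 of 20 female ones (5%; 0.127 to 24.9). Thinned to 10 counts per cell, the shares were 22.2% (2 of 9) and 0% (0 of 16, where 3 cells would be 18.8%). Among the other cells with at least 10 counts, Piezo2 was detected in 14% of male and 5.09% of female cells, without thinning. These cells were shallower: the median was 15 counts in each animal, against 35.5 in male and 32 in female glial-marker cells. The unthinned shares of glial-marker cells also include cells under 10 counts. The shares of the 2 groups are therefore not alike in depth. Over all cells, Piezo2 met any glial marker at 0.741 times the number that depth predicts in male region 0 (0.272 to 1.61). In female regions 0 and 1 the values were 0.772 (0.159 to 2.26) and 0.443 (0.163 to 0.964). Pairs of like kind also met less often than depth predicts, so a value under 1 need not mean that genes keep apart. Piezo2 showed up in 20.0% of all deep cells of male region 0, 11.7% of female region 0 and 4.70% of female region 1, and in 16.4%, 6.49% and 2.79% after thinning. All 11 deep Piezo2-positive cells of male region 0 and all 9 of female region 0 lay in cluster 0, and 0 of 59 in female region 1. Of all deep cells, 65.5%, 76.6% and 0.0796% lay there in the same order.

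Cells with Piezo2 had higher fitted levels of Ptprz1, Dlgap1 and the polarity gene Prickle2, which mark cluster 0, but no gene passed the adjusted test. The test set 11 male and 68 female Piezo2-positive cells against 48 and 1265 others (2 animals, 63 genes). edgeR called 0 genes after adjustment, 1 gene had an unadjusted p under 0.05, and DESeq2 called 0. That gene was Ptprz1, with a log2 fold change of 3.22 (p 0.0133, adjusted p 0.839) and a higher level in both animals, 2000.0 against 346 per 10000 in the male and 259 against 16.8 in the female. Within female region 0 it stood at 1318 against 222, but 1 cell gave 35 of the 39 counts of the positive cells there. That cell also gave 35 of the 40 counts of all female positive cells, so the female level rests largely on it. The female contrast also mixes its regions: region 0 gave 9 of the 68 female cells with Piezo2 and 68 of the 1265 others. Within region 0, Dlgap1 stood at 2264 per 10000 against 1254 and Prickle2 at 1149 against 516. In the 59 female cells with Piezo2 from region 1, Ptprz1 had 1 count and Dlgap1 none, and Prickle2 stood at 40.1 per 10000 against 50.8. Dlgap1 came to 1.81 and Prickle2 to 1.41. On simulated sums with this spread, edgeR recovered 32.9% of genes changed 16-fold. Over all cells of male region 0, Piezo2 met Ptprz1 at 0.630 times the number that depth predicts (0.272 to 1.24). In female regions 0 and 1 the values were 0.720 (0.148 to 2.10) and 1.48 (0.180 to 5.36), so each interval spans 1.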

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

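The items below were picked out after the results were seen. The highest blank barcodes were Blank-11 in male region 0 (9 counts), Blank-2 in female region 0 (33 counts) and Blank-28 in female region 1 (46 counts). Blank barcodes entered none of the gene comparisons. Cells with fewer than 10 panel counts, 30501 in number, were left out of the clusters and tests but held 46.6% of the panel counts. They carried 179 glial marker counts and 112 Piezo2 counts, the latter in 101 cells, 93 of them in female region 1. These transcripts entered the sums per region, and 5 of the 30 glial-marker cells lay under the minimum and entered the counts and Piezo2 shares of those cells.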

How the results depend on the processing

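The tests of glial-marker and Piezo2-positive cells, and the settings without female region 1, without the 20 deepest cells, without clusters 0, 1 and 4 and with at least 10 counts between regions or animals, were chosen after the results were seen. Clustering on all panel genes at resolution 2, and at minimums of 5 and 25 counts, was not fixed in advance either. Clusters named rose from 0 to 1 with all panel genes at resolution 1 and at resolution 2, and were 0 with all panel genes at minimums of 5 and 25 counts. edgeR calls rose from 0 to 4 for glial-marker cells with mixed cells left out, where 4 male and 1 female such cells remained, and from 0 to 3 for Piezo2-positive cells with counts per cell (smallest adjusted p 3.76e-07, and 0.286 to 0.998 under the other settings), where deeper cells gain in every gene. Piezo2 in glial-marker cells turned to -0.38 with TMM factors and -0.44 with DESeq2, and ran from -0.38 to 0.83 with 1 animal left out. In the female, its share of cells fell to 0% with at least 2 Piezo2 counts and 0% after thinning. Panel counts per cell, region 1 over region 0 in the female, went from 4.96 to 0.619 in glial-marker cells only, and female over male from 8.17 to 0.787 in those cells and to 2.21 without female region 1; the cause was not tested. Per cell, ratios turned for Syt4 between the female regions (1.06, region 1 over region 0) and, female over male, for Gfra2 (1.64), Snap25 (1.32), Gfra1 (1.16), Dlgap1 (1.37) and Pclo (1.74). Without female region 1 they turned for Gfra2 (1.07, interval spanning 1, as for Syt4, Gfra1 and Abca8b here), Snap25 (1.62), Dlgap1 (1.80) and Pclo (1.92). With at least 10 counts, Abca8b between the male regions turned to 1.35, region 1 over region 0. Counting per cell multiplies every ratio of a comparison by one factor, so it tests no gene on its own. Directions of the named genes held for 14 of 18 between animals without female region 1. Of those that held, Vim, Des, Fn1, Chd9, Piezo1 and Atp10b had intervals that span 1. Directions held for 15 of 15 that could be compared between animals without clusters 0, 1 and 4. That setting sets male cells with fewer than 10 counts only against female cells of any depth, so the 2 sides are unlike. The settings fixed in advance for glia against other classes, against neurons and for subclusters were not run, since no glia class was named. The male regions gave no value for glial-marker cells, nor did either test without clusters 0, 1 and 4, which leaves no male cell.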

Other observations

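All tests below were chosen after the results were seen, and those on the Snap25 share, the highest blank and an equal loss replaced earlier versions whose values were already known. In female region 0 the mucin Muc6 and the synaptic gene Snap25 kept apart: both are abundant there, yet they met in 4 cells, 0.0286 times the number that depth predicts (0.00780 to 0.0733). In female region 1 the epithelial gene Aqp8 and the muscle gene Des met at 0.0618 times that number. Pairs of like kind there also met less often than depth predicts, though far more often than these: Aqp8 with Slc26a3 at 0.628 times (0.582 to 0.677), Des with Dmpk at 0.751 and Fn1 with Vim at 0.699, so a ratio of this size says nothing about whether 2 genes go together. Tubb3 and Stmn2, both neuronal, met in 4 cells, 10.2 times the number predicted (2.77 to 26.1).

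Cells of cluster 0, led as a group by Snap25, Dlgap1, Ptprz1 and Pclo, were most of the deep cells in 3 regions and few of those in female region 1; Ptprz1 was found in 31% of them. Whether they are neurons with the marker mix of female region 1 is not decided. Over all cells of the 3 regions Snap25 made up 95.95% of neuronal marker counts (94.3 to 97.2), against 41.6% in female region 1 (34.5 to 48.9), but there each of the other neuronal markers lies under the highest blank, so background could set that share. Counts given to barcodes at random are argued against, since the mean blank reached 7.91% of the mean gene in cluster 0. A background that favours certain barcodes stays open and may contribute in the female, where Blank-2 took 45.2% of the blank counts in cluster 0 (29.8 to 61.3) against 13.1% in other cells of region 0 (7.34 to 20.98); in the male it took 23.5% (6.81 to 49.9) against 3.03% (0.0767 to 15.8), the same direction on too few counts to decide. Blank-2 was picked as the highest blank of cluster 0 over both animals, a choice that favours a high share there. Cells of another type, or tissue that differs between regions, also stay open and were not tested.

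Panel counts per cell were higher in female region 1 than in female region 0. An equal loss of every transcript in region 0 is argued against as the whole cause: the 5 genes with most counts there (Muc6, Snap25, Col12a1, Dlgap1 and Prickle2) had more counts per cell in region 0, with a median ratio of 13.2. This test took the place of one on the number of genes higher in region 0, after the values of both were known, and both pointed the same way. The 5 genes were picked for their counts in region 0. Snap25, Col12a1, Dlgap1 and Prickle2 are also abundant in cluster 0, where a background stays open. A loss of transcripts beside a background or a difference of tissue is therefore not excluded. A few very deep cells are argued against as well, since the ratio without the 20 deepest cells of each region was 6.06. A difference of tissue could not be tested, as the labels do not assign tissue to regions.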
